A study of Rattus norvegicus with 57 samples.

How the data were processed

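Kidney RNA was measured in 57 male Han Wistar rats, each on its own Affymetrix Rat 230 2.0 array, a one-colour platform on which biotin-labelled RNA is hybridised to probe sets of short oligonucleotides near the 3' ends of transcripts. Per the labels, the rats were 8 weeks old, received a single intraperitoneal dose of 0, 1 or 3 mg/kg cisplatin in saline, and were killed 3, 5, 8 or 26 days later. The tissue was a homogenate enriched in kidney cortex. The design text gives 6 animals per group. The arrays analysed here number 5 in each group, except 4 for the day 26 controls and 3 for 1 mg/kg on day 5. Groups, doses, days and replicate numbers were taken from the labels alone.

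The deposited values are intensity values, 1 per probe set and array, on a linear scale. They were made with MAS5, per the submitters' processing notes. Its version and its background and filter steps are not given in the sources used here. The values show a scaling of every array to the same level: the mean over probe sets, without the lowest and highest 2%, was 99.99 on every array. The table holds 31099 probe sets, of which 57 control probe sets were left out of the tests. Names came from the platform annotation, updated through Entrez gene numbers for 20758 probe sets and through accessions for 2, with the symbols of the GRCr8 RefSeq gene table used for names alone. A further 66 kept the symbol of the annotation, and 1 symbol changed in the update. Of the remaining probe sets, 20826 had 1 gene symbol, 436 had several and 9780 had none. No gene was named from a probe set with several symbols.

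All computation used log2(signal + 16), so the log2 changes of dim genes are smaller than those of their signals. A probe set was kept where it lay above the 40th percentile of its array on at least 3 arrays, which left 21829. Each gene was represented by its probe set with the highest mean log2 signal, giving 11683 genes tested. The tests used limma 3.58.1 in R 4.3.3, with a mean for each of the 12 groups fitted over all 57 arrays, contrasts between group means, and moderated variances with an intensity trend. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The standard errors given with log2 changes are those of this fit and pool the spread over all groups, whereas an SD belongs to its own group. For a gene that varies more in a compared group than in the pool, these errors and the limma p-values are too small. For one that varies less they are too large. The contrasts compared each dose with the same-day control, 3 mg/kg with 1 mg/kg on each day, the effect of 3 mg/kg between successive days, and control rats on day 26 with those on day 3. In every simulated comparison, 100 genes were changed by 0.5 and another 100 by 1 on the log2 scale among the 11683. For 3 mg/kg on day 3, 85% and 98% were recovered. For 1 mg/kg on day 5, with the fewest arrays, the shares were 72% and 99%. The noise was normal and independent between genes, with each gene's spread pooled over all groups. Recovery may be lower for genes that vary more within a compared group.

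Before the data were examined, 24 gene lists were fixed, and 23 of them had at least 3 measured genes. The exception was the adrenal list, with 1 measured gene, Nr5a1. Lists were tested with camera from limma at its preset inter-gene correlation, adjusted over the 184 tests of 23 lists in 8 comparisons, and again with a correlation estimated for each list. Of 54 calls at the preset correlation, 5 held with an estimated correlation, all for p53 target genes: 3 mg/kg on days 3, 5 and 8, and 1 mg/kg on days 3 and 8. Counts of list members are given over all genes tested and adjusted over the list alone. The genes named were set by a rule also fixed beforehand. It takes the 8 largest rises and falls among called genes with no overlap between the groups for 3 mg/kg, the 4 largest for other contrasts, 16 genes named whatever their result, and up to 4 members per list with the largest change. Genes outside it are said to be so. Havcr1, Lcn2, Clu and Cdkn1a were also tested with exact permutation tests, two-sided, adjusted over the 32 tests.

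Each array's quality was followed through the 3'/5' signal ratios of the actin and GAPDH control probe sets. Actin ratios ran from 4.47 to 8.58 and GAPDH ratios from 1.28 to 1.71. Median signal per array ran from 20.3 to 26.2, and between 40.6% and 46.3% of probe sets lay under a signal of 16. The number of arrays limits the precision. Within groups, arrays correlated at 0.961 to 0.993, so no pair was treated as a repeat of the same sample.

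Alternatives fixed beforehand were no offset with signals under 1 set to 1, an offset of 64, quantile normalization, centring on the 75th percentile, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every kept probe set, eBayes without trend or with robust estimation, fits of the compared groups alone, array weights, the replicate number as a block, and each array left out in turn. The replicate numbers were checked for pairing and marked no shared animal. Added after the data were seen were the actin ratio as a covariate, the Alb signal as a covariate, and 1 mg/kg on day 8 without 2 arrays that stood apart on the principal components. The immediate early list was refitted with the actin or the GAPDH ratio as a covariate, without those 2 arrays, and without each array in turn. Lists of very long genes, liver transcripts, clock genes and immediate early genes were also written after the data were seen, and the clock and immediate early lists were tested without the members seen before. Gene lengths and coordinates are not given here, since no genome build is named for these arrays. The list of very long genes came from general knowledge.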

Results

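Gene expression in rat kidney cortex was followed for 26 days after a single dose of cisplatin, a platinum compound that crosslinks DNA and injures the renal tubule. The 57 animals fell into 12 groups of 3 to 5 defined by dose (0, 1 or 3 mg/kg) and day (3, 5, 8 or 26). Signals had been scaled to a common level by the authors, with array medians of 20.3 to 26.2. Values are log2 changes of (signal + 16) against same-day controls, with the standard error of the fit, unless stated. The comparisons asked which transcripts moved with dose at each time and which had returned towards control levels by day 26.

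At 3 mg/kg the count of changed genes was 1151 on day 3, 1028 on day 5, 4360 on day 8 and 88 on day 26. At 1 mg/kg the counts were 11, 2, 61 and 1. The first principal component held 23.8% of the variance, and the 3 mg/kg day 8 animals had the highest scores on it, from 18.8 to 43.

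**Figure D1:**
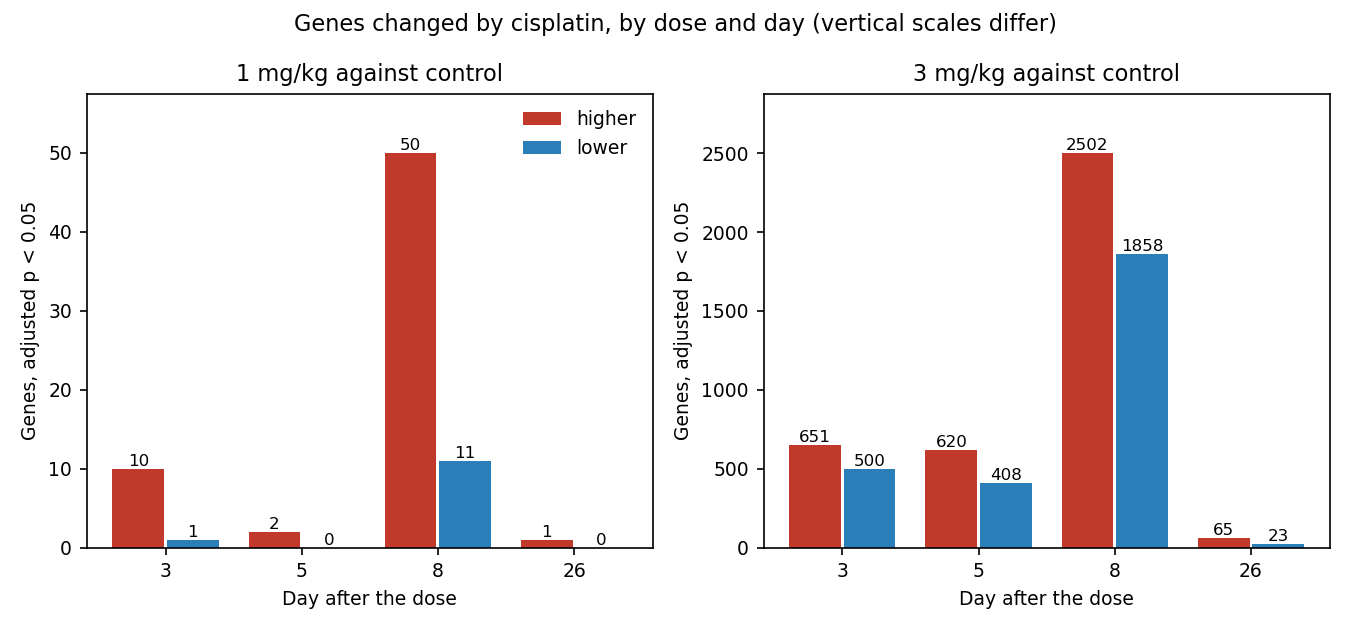
Number of genes with adjusted p under 0.05 against same-day controls (vertical axis, separate scale per panel) by day (horizontal axis), for 1 mg/kg on the left and 3 mg/kg on the right. Red bars are genes higher and blue bars genes lower than control; on day 8 at 3 mg/kg they number 2502 and 1858.

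On day 3 after 3 mg/kg, Havcr1, which encodes the tubular injury protein KIM-1, rose by 3.47 ± 0.62 (adjusted p = 0.000194, n = 5 per group), above every control in 5 of 5 animals. Genes transcribed under p53 rose together: Cdkn1a, the cell cycle inhibitor p21, by 2.09 ± 0.19 (adjusted p = 1.33e-11), Plk2 by 2.0 ± 0.14, Ccng1 by 1.84 ± 0.09 and Phlda3 by 1.76 ± 0.13. Mdm2, which encodes the ligase that degrades p53, rose by 1.07 ± 0.08. The immediate early factor Egr1 rose by 1.92 ± 0.35, the clock repressor Nr1d1 by 1.77 ± 0.24 and the glutathione peroxidase Gpx2 by 1.57 ± 0.39. Among genes with no overlap between the groups, the largest falls were in Gtpbp4 (-1.59 ± 0.39), beta-globin Hbb (-1.47 ± 0.33), regucalcin Rgn (-1.45 ± 0.37), Hba-a3 (-1.27 ± 0.34) and Slc7a12 (-1.21 ± 0.33). Immp2l (-1.17 ± 0.18), Rnf125 (-1.15 ± 0.21) and the pyrimidine-degrading enzyme Dpyd (-1.13 ± 0.12) followed.

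Of 22 measured p53 target genes, 12 rose and 1 fell on day 3 at 3 mg/kg (16 and 1 adjusted over the list alone). Their median was 0.37, with adjusted p = 8.49e-17 in camera and adjusted p = 0.000337 with an estimated correlation. The member that fell was Sesn1, a stress-induced sestrin, at -0.45. Among 17 antioxidant and metallothionein genes, 5 rose (6 over the list alone), including Nqo1 by 0.81 ± 0.16 and Srxn1 by 0.75 ± 0.21 (adjusted p = 0.0272; adjusted p = 0.567 with an estimated correlation). In the DNA replication list 3 of 21 rose, Cdt1 by 0.49, Mcm7 by 0.43 and Tyms by 0.42 (5 over the list alone; adjusted p = 0.0105; adjusted p = 0.742 with an estimated correlation). Of 14 endoplasmic reticulum stress genes, 3 rose, among them Ddit3 by 0.43 and Trib3 by 0.37 (4 over the list alone; adjusted p = 0.027; adjusted p = 0.599 with an estimated correlation). In the DNA repair list, Ercc2 and Ercc4 rose by 0.41 and 0.27, 2 of 11 members (4 over the list alone; adjusted p = 0.0493; adjusted p = 0.266 with an estimated correlation).

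Markers of blood moved as well: Hbb and Alas2 (-0.92 ± 0.24) fell, 2 of 4 blood cell genes (2 over the list alone; median -0.63, adjusted p = 0.011; adjusted p = 0.163 with an estimated correlation). Cholesterol synthesis genes had a median of -0.18 with 0 of 12 members passing in limma and 0 over the list alone (adjusted p = 0.0125; adjusted p = 0.737 with an estimated correlation). In limma Lcn2 (0.43, adjusted p = 0.443), Clu (0.16, 0.83), Spp1 (0.44, 0.341) and Umod (0.13, 0.904) did not pass on day 3. In the exact permutation test Lcn2 did, above every control in 5 of 5 animals (exact p = 0.00794, adjusted p = 0.0149). The actin 3'/5' ratio was 5.89 ± 0.10 (SD, n = 5) in this group and 4.66 ± 0.25 in its controls. With that ratio as a covariate the count of 1151 was 499, and with the Alb signal as a covariate it was 676, alternatives chosen after seeing the data. The actin ratio did not overlap between these groups, so the count of 499 does not show which genes follow RNA quality.

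After 1 mg/kg, 10 genes were higher and 1 lower on day 3 (704 at an unadjusted p under 0.05). Ccng1 rose by 0.99 ± 0.09 (adjusted p = 3.63e-10, n = 5 per group), Plk2 by 0.97 ± 0.14, Phlda3 by 0.77 ± 0.13, Mdm2 by 0.37 ± 0.08 and Nr1d1 by 1.31 ± 0.24, while the oxidoreductase gene Wwox fell by 0.60 on the log2 scale. Of the p53 target genes 5 rose (8 over the list alone; median 0.14, adjusted p = 9.13e-10, and adjusted p = 0.00847 with an estimated correlation). Cdkn1a (0.68, adjusted p = 0.259) and Havcr1 (2.17, adjusted p = 0.261) did not pass in limma. Endoplasmic reticulum stress genes had a median of 0.17 with 0 passing (5 over the list alone; adjusted p = 3.17e-08, and adjusted p = 0.0505 with an estimated correlation). Antioxidant genes, with 0 passing and 1 over the list alone, gave adjusted p = 0.0196 (adjusted p = 0.567 with an estimated correlation). Blood cell genes, median -0.30 with 0 passing, gave adjusted p = 0.0462 (adjusted p = 0.352 with an estimated correlation). The actin ratio was 5.09 ± 0.30 (SD, n = 5) in this group and 4.66 ± 0.25 in its controls. The count of changed genes was 7 without control day 3 replicate 1 and 7 without 1 mg/kg day 3 replicate 2.

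Compared directly on day 3, 365 genes differed between the doses, 182 higher and 183 lower at 3 mg/kg. Cdkn1a was higher by 1.42, Plk2 by 1.04, Phlda3 by 1.00 and Foxl2 by 0.99, and Cndp1 (-1.32), Slc7a12 (-1.23), Adgrv1 (-1.0) and Prep (-0.85) were lower. The count was 175 with the actin ratio as a covariate, 105 with Alb, 1047 with array weights and 784 over all kept probe sets. Leaving out 1 mg/kg replicates 1, 2, 3 or 4 gave 196, 179, 191 or 184, and leaving out 3 mg/kg replicates 1, 4 or 5 gave 194, 189 or 215.

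On day 5 after 3 mg/kg, further injury transcripts passed in limma beside the p53 targets. Havcr1 rose by 4.85 ± 0.62 (adjusted p = 3.04e-07, n = 5 per group), osteopontin Spp1 by 2.31 ± 0.29, the fibrinogen chain Fga by 1.84 ± 0.28, clusterin Clu by 1.64 ± 0.38, the iron-binding lipocalin Lcn2 by 1.63 ± 0.34 and the metalloproteinase inhibitor Timp1 by 1.01 ± 0.29. Further rises were in the glucuronosyltransferase Ugt2b7 (2.49 ± 0.53), Cdkn1a (2.29 ± 0.19), Angptl4 (1.95 ± 0.35), Akr1b8 (1.79 ± 0.55), Plk2 (1.73 ± 0.14) and Ccng1 (1.73 ± 0.09). Falls were smaller, and among genes with no overlap between the groups the largest were in the Wnt antagonist Sfrp2 (-1.17 ± 0.27) and Wwox (-0.90 ± 0.11). These were followed by Ces1e -0.84 ± 0.19, Nrep -0.82 ± 0.21, Pappa2 -0.82 ± 0.12, Tgm2 -0.79 ± 0.15, Ppard -0.72 ± 0.11 and Capn6 -0.70 ± 0.15. Among segment genes, Calb1 of the distal tubule fell by 0.51 on the log2 scale, while Umod (-0.08, adjusted p = 0.95) and Egf (-0.49, adjusted p = 0.439) did not pass.

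Of 23 kidney injury markers, 13 rose on day 5 (17 over the list alone; median 0.60, adjusted p = 1.17e-13; adjusted p = 0.106 with an estimated correlation). Of the p53 targets, 14 rose and Sesn1 fell (14 and 1 over the list alone; median 0.47, adjusted p = 8.09e-16, and adjusted p = 0.000348 with an estimated correlation). DNA replication genes rose in 8 of 21 (11 over the list alone), among them Mcm6 by 0.67 and Rfc4 by 0.50 (adjusted p = 1.79e-07; adjusted p = 0.266 with an estimated correlation). Of 24 mitosis genes only Aurkb passed, at 0.48 (1 over the list alone; list adjusted p = 0.000607; adjusted p = 0.742 with an estimated correlation). Antioxidant genes rose in 7 of 17 (8 over the list alone), with Gstp1 at 1.22 and Srxn1 at 0.94 (adjusted p = 7.26e-06; adjusted p = 0.106 with an estimated correlation). Chemokine and inflammation genes rose in 5 of 18 (6 over the list alone), Ccl20 by 1.49 and Ccl2 by 0.97 among them (adjusted p = 0.00113; adjusted p = 0.381 with an estimated correlation). In the endoplasmic reticulum stress list 1 of 14 rose (3 over the list alone; adjusted p = 0.0183; adjusted p = 0.567 with an estimated correlation). The actin ratio was 5.42 ± 0.38 and that of the controls 5.07 ± 0.39, and the count of 1028 was 547 without 3 mg/kg day 5 replicate 1.

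After 1 mg/kg, 2 genes passed on day 5, Plk2 at 0.82 ± 0.16 (adjusted p = 0.0167) and Ccng1 at 0.64 ± 0.11 (adjusted p = 0.00421; n = 3 against 5), with 376 at an unadjusted p under 0.05. Havcr1 was at 0.84 and Cdkn1a at 0.75 (adjusted p = 1 for each in limma). The p53 list, with 2 of 22 higher (4 over the list alone), gave adjusted p = 2.5e-05 and adjusted p = 0.106 with an estimated correlation. Mitosis genes, 0 of which passed over all genes or the list alone, gave adjusted p = 0.00126 and adjusted p = 0.757 with an estimated correlation. The count of 2 became 1 without control day 5 replicate 2, 3 or 5 or 1 mg/kg replicate 3, and 0 without 1 mg/kg replicate 1 or 2. Between the doses, 464 genes differed on day 5 (303 higher, 161 lower at 3 mg/kg). Havcr1 was higher by 4.01 ± 0.72, Ugt2b7 by 2.28, Angptl4 by 1.95 and Fga by 1.87, and Wwox (-0.94), Cmklr1 (-0.78), P2ry1 (-0.67) and Pappa2 (-0.66) lower. That count was 209, 185 or 175 without 1 mg/kg replicate 1, 2 or 3, 183 without 3 mg/kg replicate 1, and 183 in a fit of these 2 groups alone.

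**Figure D2:**
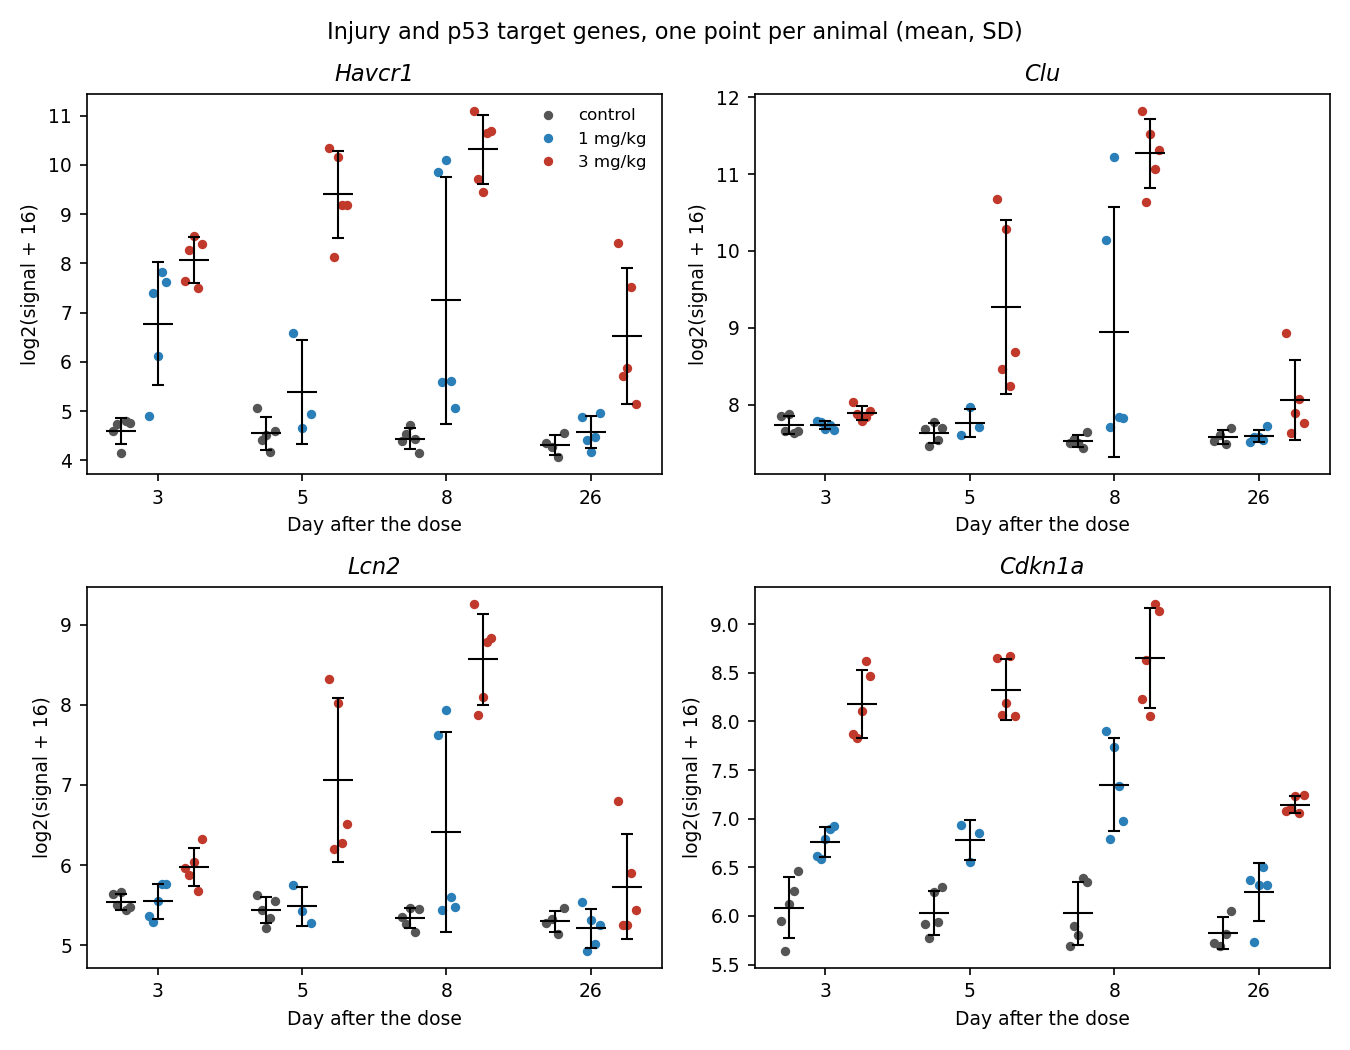
Signals of Havcr1, Clu, Lcn2 and Cdkn1a on the log2(signal + 16) scale (vertical axes) by day (horizontal axis), 1 point per animal, with black lines for the group mean and its SD. Grey points are controls, blue 1 mg/kg and red 3 mg/kg; at 1 mg/kg on day 8 the Havcr1 signals ran from 17.6 to 1085.

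On day 8 after 3 mg/kg the kidneys showed their widest changes, with 2502 genes higher and 1858 lower, 37.3% of those tested, and 276 changed at least 2-fold. Injury transcripts reached Havcr1 5.88 ± 0.62 (adjusted p = 1.63e-10, n = 5 per group), Clu 3.74 ± 0.38, Lcn2 3.23 ± 0.34, Gpnmb 2.92 ± 0.30, Fga 2.81 ± 0.28, Fgb 2.78 ± 0.26 and the TWEAK receptor gene Tnfrsf12a 2.72 ± 0.25, with Ugt2b7 at 2.95 ± 0.53. The mean Havcr1 signal was 1380 ± 620 (SD, n = 5) against 5.94 ± 3.13 in controls. The largest fall was in Umod (-4.71 ± 0.52, adjusted p = 5.65e-10), which encodes uromodulin of the thick ascending limb. It was followed by the organic anion transporters Slco1a6 (-3.78 ± 0.43), Slco1a1 (-3.58 ± 0.27) and Slco1a3 (-2.73 ± 0.37), and by Egf (-3.52 ± 0.36), Tff3 (-3.48 ± 0.41), Ppp1r1a (-3.47 ± 0.35) and the histamine-degrading enzyme Hnmt (-3.24 ± 0.41).

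The depth of the Umod fall varied between animals, and its signals were 785.5, 2.68, 921, 21.6 and 5.37 in replicates 1 to 5, against a control mean of 2670 ± 303 (SD, n = 5). The SD of the log2 Umod signal was 2.84 at 3 mg/kg and 0.16 in controls. The error and adjusted p given above for Umod pool all groups and are too small for this spread. Of 11 loop of Henle and distal tubule genes, 8 fell and 1 rose (8 and 1 over the list alone; median -1.67, adjusted p = 3.49e-07; adjusted p = 0.266 with an estimated correlation). The falls included the sodium-potassium-chloride cotransporter Slc12a1 (-2.66 ± 0.41) and kallikrein Klk1 (-2.13 ± 0.20), while the calcium channel gene Trpv5 rose by 1.13 ± 0.14. Collecting duct genes fell in 4 of 12 and rose in 1 (6 and 1 over the list alone), with Hsd11b2 at -0.91 ± 0.10 and the water channel Aqp2 at -0.89 ± 0.23 (adjusted p = 0.0168; adjusted p = 0.567 with an estimated correlation).

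Proximal tubule genes went in both directions on day 8. Of 28 transporters, 9 fell and 6 rose (9 and 7 over the list alone; list median 0.00, adjusted p = 0.538): Slc22a2, the organic cation transporter that takes up cisplatin, fell by 1.85 on the log2 scale and Slc7a13 by 2.51, whereas the efflux pump Abcc2 rose by 2.70 ± 0.26. Slc22a6 (-0.08, adjusted p = 0.551) and Slc34a1 (0.16, adjusted p = 0.1) did not pass. Of 20 proximal tubule enzymes, 6 fell, including the brush border peptidases Mme (-1.70 ± 0.26) and Anpep (-1.32 ± 0.12), and 5 rose, Cyp27b1 by 1.39 ± 0.23 (7 and 6 over the list alone; list adjusted p = 0.451). Fatty acid oxidation genes rose in 10 of 21 and fell in 3 without passing as a list (10 and 3 over the list alone; adjusted p = 0.0882), with Ehhadh at 1.21 and Eci1 at 0.93.

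**Figure D3:**
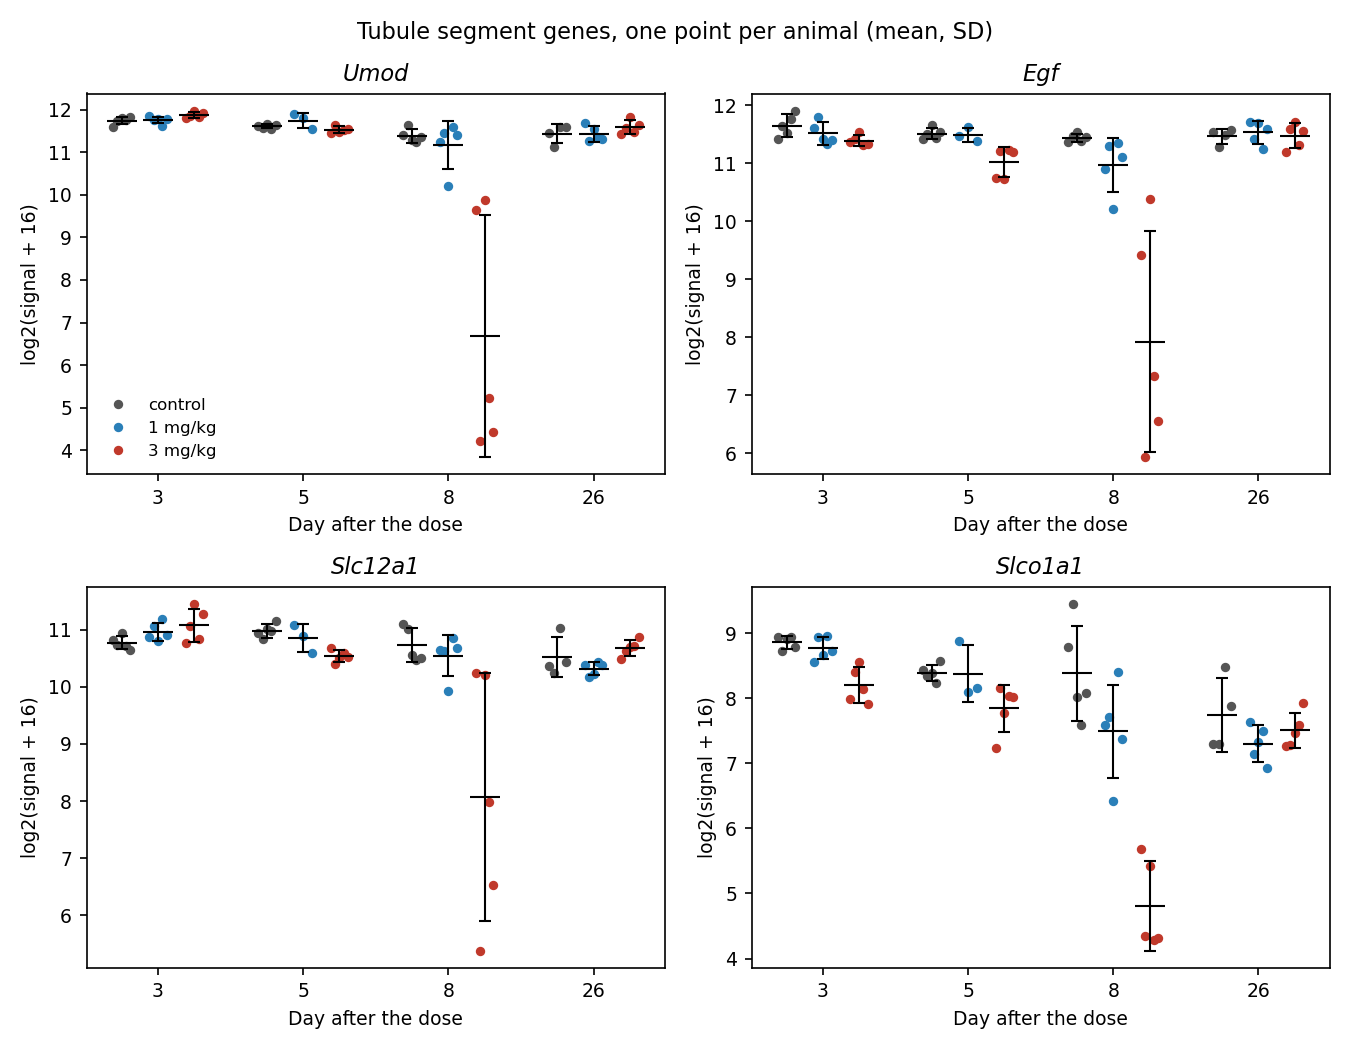
Signals of Umod, Egf, Slc12a1 and Slco1a1 on the log2(signal + 16) scale (vertical axes) by day (horizontal axis), 1 point per animal, with black lines for the group mean and its SD. Grey points are controls, blue 1 mg/kg and red 3 mg/kg; the Umod signals of the 3 mg/kg animals on day 8 ran from 2.68 to 921.

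Dividing-cell transcripts were higher on day 8 at 3 mg/kg: 21 of 24 mitosis genes rose (22 over the list alone; median 0.55, adjusted p = 2.05e-06; adjusted p = 0.567 with an estimated correlation). Top2a was at 0.75 ± 0.19 and Mki67 at 0.70 ± 0.18. Of the DNA replication genes 12 of 21 rose (14 over the list alone; adjusted p = 0.00511; adjusted p = 0.7 with an estimated correlation). Of the p53 targets, 16 rose and Sesn1 fell (16 and 1 over the list alone; median 0.55, adjusted p = 1.84e-09, and adjusted p = 0.00847 with an estimated correlation). Kidney injury markers rose in 20 of 23, and Tff3 fell (20 and 1 over the list alone; median 1.48, adjusted p = 8.49e-17; adjusted p = 0.0519 with an estimated correlation). Fibroblast and matrix genes rose in 11 of 22 (11 over the list alone), with list adjusted p = 0.000207 and adjusted p = 0.549 with an estimated correlation. Lox rose by 1.54, Tagln by 1.53 and Dcn by 1.21, whereas Col1a1 was at 0.17 (adjusted p = 0.406). Macrophage and myeloid genes rose in 10 of 17 (10 up and 1 down over the list alone), Mrc1 by 0.97 and Cd68 by 0.75 (adjusted p = 0.00113; adjusted p = 0.7 with an estimated correlation). Antioxidant genes rose in 9 of 17 and fell in 3 (10 and 3 over the list alone), Srxn1 by 2.17 against Gclc at -1.43 (adjusted p = 0.0196; adjusted p = 0.567 with an estimated correlation). Cholesterol synthesis genes fell in 6 of 12 (6 over the list alone), Idi1 at -0.75 and Cyp51 at -0.61 (adjusted p = 0.00909; adjusted p = 0.703 with an estimated correlation).

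Markers of other cells and tissues on day 8 at 3 mg/kg passed in 3 of 11 endothelial genes, all lower (Vwf -0.63, Tie1 -0.56, Emcn -0.47). They passed in Tcf21 (0.31), Podxl (-0.25) and Wt1 (-0.23) of 9 podocyte genes, and in S100a9 (1.13) and S100a8 (0.59) of 4 blood cell genes. Aqp4 (0.95) and Slc5a3 (-0.57) passed among 4 inner medulla genes, Cidec (-0.69) among 3 adipocyte genes, and 0 of 9 lymphocyte genes in limma. The counts over each list alone were equal to these, and no list adjusted p was under 0.321. Chemokine genes rose in 7 of 18 (8 over the list alone; list adjusted p = 0.18), endoplasmic reticulum stress genes in 6 of 14 with 2 lower (7 and 2 over the list alone; 0.391). Interferon genes rose in 1 of 16 with 2 lower (1 and 2; 0.538) and DNA repair genes in 2 of 11 (2; 0.65). The actin ratio was 5.30 ± 0.53 and that of the controls 5.32 ± 0.48. The count of 4360 was 2553 in a fit of the compared groups alone and 6931 over all kept probe sets.

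At 1 mg/kg, 50 genes were higher and 11 lower on day 8. Havcr1 rose by 2.80 ± 0.62 (adjusted p = 0.0178, n = 5 per group), Fos by 1.85 ± 0.40, Spp1 by 1.77 ± 0.29, Atf3 by 1.65 ± 0.28, Cdkn1a by 1.32 ± 0.19 and Plk2 by 0.87 ± 0.14, and Sfrp2 (-1.14 ± 0.27), Ap4s1 (-0.54), Sec11c (-0.30) and Cgrrf1 (-0.30) fell. The animals differed widely: Havcr1 signals were 911.8, 32.4, 1085, 32.9 and 17.6 in replicates 1 to 5, and the SD of the log2 signal was 2.51. The Havcr1 error of 0.62 pools all groups, so it and its adjusted p do not reflect the spread of this group. Clu (1.42, adjusted p = 0.0638), Lcn2 (1.08, adjusted p = 0.142) and Umod (-0.21, adjusted p = 0.912) did not pass in limma.

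Of the p53 targets 6 rose on day 8 at 1 mg/kg (9 over the list alone; median 0.25, adjusted p = 9.95e-10, and adjusted p = 0.00847 with an estimated correlation). Of the injury markers 3 rose (13 over the list alone; adjusted p = 7.6e-10; adjusted p = 0.218 with an estimated correlation). Chemokine genes rose in 2 of 18 (6 over the list alone), Cxcl1 by 0.73 and Cxcl10 by 0.71 (adjusted p = 1.68e-05; adjusted p = 0.163 with an estimated correlation). Myeloid genes, with a median of 0.27 and 0 of 17 passing (3 over the list alone), gave adjusted p = 9.1e-05, or adjusted p = 0.567 with an estimated correlation. Lists for mitosis, DNA replication, fibroblasts, lymphocytes, endoplasmic reticulum stress and cholesterol synthesis were also called at the preset correlation, and their adjusted p with an estimated correlation ran from 0.538 to 0.783. The actin ratio was 6.09 ± 1.51, with the highest array at 8.58. The count of 61 was 25 or 20 without control day 8 replicate 2 or 3, and 34, 127, 12 or 112 without 1 mg/kg replicate 1, 2, 3 or 4. It was 11 without replicates 1 and 3, an alternative chosen after seeing the data under which the fibroblast list turned from a median of 0.14 to -0.08 (adjusted p = 0.0471; adjusted p = 0.772 with an estimated correlation). A fit of the compared groups alone gave 4.

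Directly compared on day 8, 2704 genes differed between the doses (1412 higher and 1292 lower at 3 mg/kg). Abcc2 was higher by 2.40, Fga by 2.21, Srxn1 by 1.73 and Timp1 by 1.67, and Umod (-4.50), Slco1a1 (-2.69), Tmem86a (-2.18) and Matn1 (-1.92) were lower. In a fit of these groups alone the count was 535.

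On day 26 at 3 mg/kg, 0 of 11 loop of Henle and distal tubule genes, 0 of 12 collecting duct genes, 0 of 28 proximal tubule transporters and 0 of 20 proximal tubule enzymes passed in limma, with 0 in each over the list alone. Their medians were 0.06, -0.03, 0.01 and 0.05, with list adjusted p = 0.492, 0.298, 0.998 and 0.78; the mean of the first list was -0.02 and its test pointed down. Umod was at 0.15 ± 0.55, Egf at 0.00 ± 0.38 and Slc22a2 at -0.02 ± 0.21. These errors leave room for changes of that size, but they pool the spread over all groups. On day 26 itself the SD of the log2 Umod signal was 0.16 at 3 mg/kg and 0.23 in controls. For Egf it was 0.22 and 0.13. Genes that rose included Cdkn1a (1.32 ± 0.20, adjusted p = 0.000401, n = 5 against 4), above every control in 5 of 5 animals, Plk2 (0.69 ± 0.14) and Phlda3 (0.64 ± 0.14). Egr1 rose by 1.97 ± 0.37, Egr2 by 1.38 ± 0.30, Atf3 by 1.29 ± 0.30, Myc by 1.00 ± 0.23 and Dusp1 by 0.97 ± 0.23, with the helicase gene Ddx60 at 1.19 ± 0.25 and the histocompatibility gene RT1-T24-3 at 0.98 ± 0.24. Among genes with no overlap between the groups, the falls named were at most 0.54 in size. These were Rsrp1 -0.54, Entr1 -0.47, Yaf2 -0.43, Gprc5c -0.38, Slc35f5, Skap2 and ST7 -0.37 each, and C14h4orf19 -0.35. Havcr1 was at 2.22 ± 0.66 (adjusted p = 0.0771), Spp1 at 1.02 ± 0.31 (adjusted p = 0.0774) and Irf7 at 1.02 ± 0.28 (adjusted p = 0.062).

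Of the p53 targets 5 rose on day 26 (10 over the list alone; median 0.22, adjusted p = 5.21e-05; adjusted p = 0.127 with an estimated correlation). Interferon response genes had a median of 0.54, with 0 of 16 passing over all genes and 10 over the list alone (adjusted p = 4.11e-08; adjusted p = 0.309 with an estimated correlation). Mx1 and Isg15 lay at 0.82 and 0.70. The median of myeloid genes was 0.32 (8 of 17 over the list alone; adjusted p = 7.26e-06, adjusted p = 0.538 with an estimated correlation). For fibroblast genes it was 0.28 (5 of 22; adjusted p = 7.54e-05, adjusted p = 0.538 with an estimated correlation). Cd3g rose by 0.56, 1 of 9 lymphocyte genes (3 over the list alone; adjusted p = 0.00456; adjusted p = 0.477 with an estimated correlation). Injury markers had 0 of 23 passing and 5 over the list alone (adjusted p = 0.00683; adjusted p = 0.742 with an estimated correlation). Podocyte genes (0 of 9, 3 over the list alone; median 0.12; adjusted p = 0.0217; adjusted p = 0.567 with an estimated correlation) and fatty acid oxidation genes (0 of 21, 0 over the list alone; median -0.10; adjusted p = 2.5e-05; adjusted p = 0.549 with an estimated correlation) had smaller medians. In limma 1857 genes had an unadjusted p under 0.05.

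The actin ratio on day 26 was 5.79 ± 0.72 and the GAPDH ratio 1.504 ± 0.125 at 3 mg/kg, against 5.10 ± 0.57 and 1.38 ± 0.04 in controls. The count of 88 was 26 with the actin ratio as a covariate, 33 after quantile normalization and 8 in a fit of the compared groups alone. It was 12 or 21 without control replicate 1 or 4, and 18, 209, 41, 23 or 49 without 3 mg/kg replicate 1, 2, 3, 4 or 5. At 1 mg/kg only Apol3-ps1 passed on day 26, at 0.59 ± 0.11 (adjusted p = 0.0372), with 776 genes at an unadjusted p under 0.05. Lists of p53 targets, fibroblasts (median 0.25), myeloid cells, lymphocytes, interferon response (median 0.26) and collecting duct were called at the preset correlation, and their adjusted p with an estimated correlation ran from 0.244 to 0.804. That count was 0 without control replicate 1 or 4 or without 1 mg/kg replicate 2, 3 or 5, 2 without 1 mg/kg replicate 1 and 3 without control replicate 3. Between the doses, 0 genes passed on day 26 in limma, with 1197 at an unadjusted p under 0.05. The count was 1 without 1 mg/kg replicate 4 or 3 mg/kg replicate 1 or 5, 12 without 1 mg/kg replicate 5, 21 without 3 mg/kg replicate 2 and 56 with array weights.

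**Figure D4:**
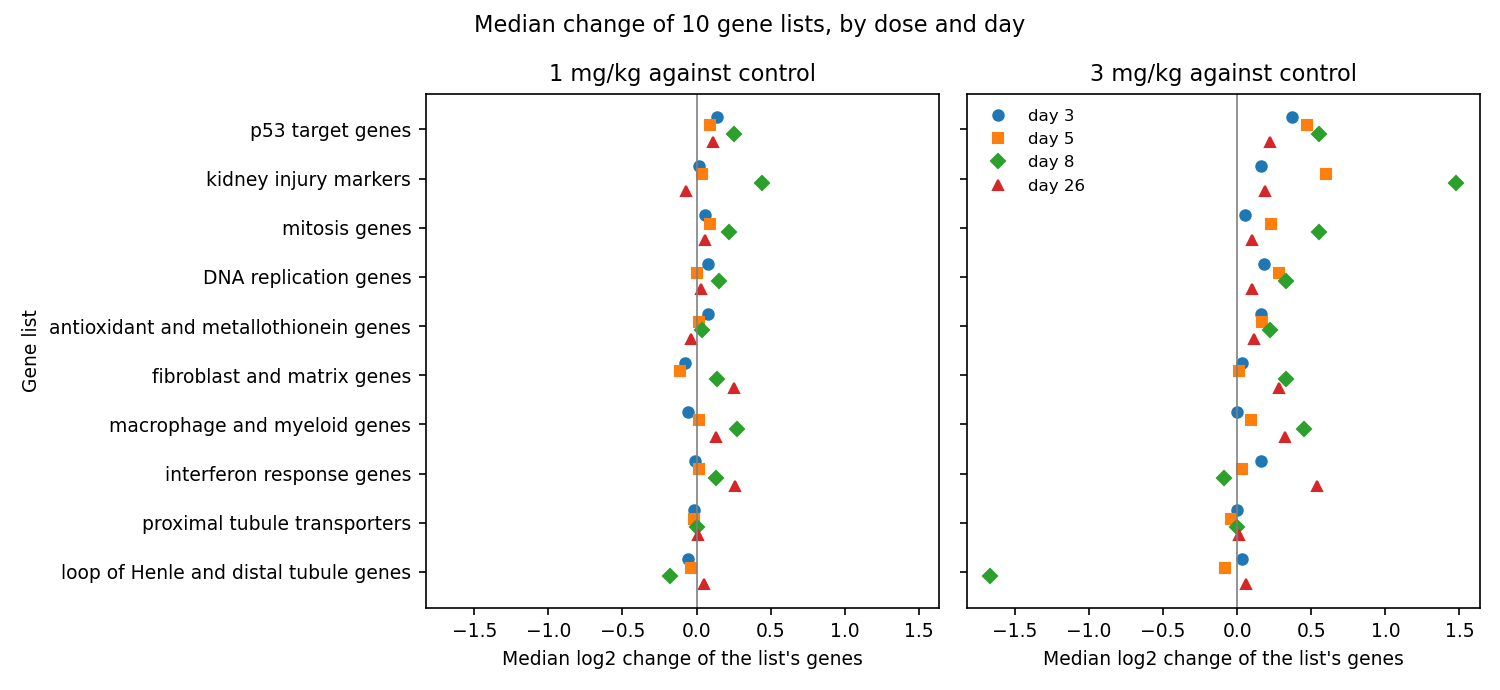
Median log2 change of the members of 10 gene lists against same-day controls (horizontal axis), by list (vertical axis), with 1 marker per day, for 1 mg/kg on the left and 3 mg/kg on the right. The highest median is that of the kidney injury markers on day 8 at 3 mg/kg (1.48), and the lowest that of the loop of Henle and distal tubule genes (-1.67).

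Tested as a change of the effect between days, 3 mg/kg differed in 177 genes between days 3 and 5, in 1909 between days 5 and 8 and in 1748 between days 8 and 26. The arrays of days 5 and 8 also differ in the log2 ratio of the BioB to the Cre control probe sets, given below. Whether that bears on the change of effect was not tested. From day 3 to day 5 the effect on Spp1 grew by 1.88, on Fga by 1.84, on Olr1 by 0.92 and on Rrp15 by 0.87, and it shifted by -1.14 for Ros1, -1.05 for Chmp2b, -0.92 for Cul4a and -0.87 for Plcl1. From day 5 to day 8 it grew by 3.13 for the retinol carrier Rbp4, 2.10 for Clu, 2.04 for Gpnmb and 2.04 for Abcc2. Rbp4 differed widely between the 3 mg/kg animals on day 8 (log2 mean 8.62 ± 3.24, SD, n = 5). The effect shifted by -4.63 for Umod, -3.36 for Tff3, -3.18 for Slco1a6 and -3.13 for Ppp1r1a. From day 8 to day 26 it turned back by 4.85 for Umod, 3.60 for Slco1a6, 3.52 for Egf and 3.38 for Ppp1r1a. It turned back by -3.66 for Havcr1, -3.26 for Clu, -2.97 for Ugt2b7 and -2.96 for Rbp4. The count of 177 was 63 with the actin ratio and 57 with Alb as a covariate, and 381 with array weights. It was 102 or 83 without control day 3 replicate 3 or 5, 87, 87 or 83 without control day 5 replicate 2, 3 or 4, 90 or 108 without 3 mg/kg day 3 replicate 1 or 3, and 104, 97 or 67 without 3 mg/kg day 5 replicate 1, 2 or 3.

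Exact permutation tests of Havcr1, Lcn2, Clu and Cdkn1a passed in 19 of 32 cases after adjustment. At 3 mg/kg Havcr1 and Cdkn1a passed on all 4 days, with Havcr1 on day 26 at exact p = 0.0159 (adjusted p = 0.0282) and Cdkn1a at exact p = 0.00794, the smallest the design allows. Lcn2 passed on days 3, 5 and 8 (0.43, 1.63 and 3.23) and Clu on days 5 and 8 (1.64 and 3.74), each above every control in 5 of 5 animals (exact p = 0.00794, adjusted p = 0.0149). Clu on day 3 (0.16, exact p = 0.0794, adjusted p = 0.106) and on day 26 (0.48, exact p = 0.0556, adjusted p = 0.0808) and Lcn2 on day 26 (0.43, exact p = 0.286, adjusted p = 0.339) did not pass. At 1 mg/kg Havcr1 passed on days 3 and 8, Cdkn1a on days 3, 5 and 8 and Clu on day 8, with Cdkn1a on day 5 at exact p = 0.0179, the smallest that 3 against 5 animals allow (adjusted p = 0.0301). Lcn2 on day 8 at 1 mg/kg stayed above the threshold (1.08, exact p = 0.0317, adjusted p = 0.0508, higher than every control in 4 of 5 animals).

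The 2 doses share control arrays, which alone correlates their effects across genes (genes are not independent replicates). The correlation was 0.589 on day 3, 0.344 on day 5, 0.662 on day 8 and 0.624 on day 26. Unchanged groups with simulated shared controls gave 0.499, 0.433, 0.497 and 0.559. Both were drawn as noise independent between genes, with each gene's spread pooled over all groups. The simulations thus leave out the spread of a given day and the correlation between genes. With the real controls split between the doses the correlation was 0.281, 0.083, 0.492 and 0.155. The covariance was 0.0149, 0.0082, 0.0395 and 0.0137 against simulated values of 0.0068, 0.0068, 0.0068 and 0.0086. Of the genes higher at 1 mg/kg, those also higher at 3 mg/kg were 9 of 10 on day 3, 2 of 2 on day 5, 46 of 50 on day 8 and 1 of 1 on day 26, where independent lists give 0.557, 0.106, 10.7 and 0.00556. Of those lower, 1 of 1 on day 3 and 10 of 11 on day 8 were shared (independent lists: 0.0428 and 1.75), and 0 genes went opposite ways. Independent lists leave out the shared controls. In 100 such simulations of unchanged groups, top-ranked lists of the observed sizes shared 5.53, 1.0, 39.0 and 0.34 higher genes on average, at most 8, 2, 45 and 1. For lower genes they shared 0.63 on day 3 and 8.82 on day 8, at most 1 and 11. The 9 and 46 shared higher genes on days 3 and 8 lay 1 above the highest simulated values, a margin that rests on this simplified noise. After adjustment, the simulated groups shared 0 calls on every day. Unchanged groups rarely give any call after adjustment, so this 0 is no measure for the shared counts. With the controls split, the covariance was 0.0089, 0.0025, 0.0335 and 0.0047.

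In control rats, 76 genes were higher and 161 lower on day 26 than on day 3, with 29 lower at least 2-fold. The arrays of these days also differed in the log2 ratio of the BioB to the Cre control probe sets. It ran from -5.44 to -5.17 on the day 3 control arrays and from -8.35 to -8.02 on the day 26 ones. Over all doses it lay between -5.79 and -5.17 on days 3 and 5 and between -9.18 and -7.84 on days 8 and 26. Time and such a difference between the arrays cannot be told apart here. Albumin, Alb (-4.01 ± 0.33, adjusted p = 2.62e-12, n = 4 against 5), Rup2 (-2.89 ± 0.31), the vitamin D carrier Gc (-1.76 ± 0.50) and Hnmt (-1.58 ± 0.43) were lower, and Dusp15 (0.76), the clock gene Per2 (0.75), Akr1c1 (0.54) and Steap1 (0.54) were higher. Alb signal averaged 315 ± 129 (SD) in day 3 controls, 514 ± 599 at 1 mg/kg and 147 ± 77.2 at 3 mg/kg on that day. It averaged between 1.89 and 6.44 in the other groups. The count of 237 was 2 with the Alb signal as a covariate, chosen after seeing the data, and 118 in a fit of the 2 groups alone. Alb itself separates these groups, at log2 8.26 ± 0.65 on day 3 and 4.26 ± 0.18 on day 26 (SD). That covariate therefore takes up the contrast, and the count of 2 does not show that the genes follow Alb. The count of 237 was 92 or 157 without day 3 replicate 3 or 4 and 66, 105 or 147 without day 26 replicate 1, 2 or 4.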

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

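The tests of the GAPDH ratios and the count of probe sets without a gene name were chosen only after the results were seen. The effect of 3 mg/kg on gene expression differed between days by a test of the difference itself, in 177 genes between days 3 and 5, 1909 between days 5 and 8 and 1748 between days 8 and 26.

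In 14 of 209 groups of 4 or 5 arrays, 1 array stood apart from the rest, measured as its gap to the nearest other array over the range of the group; chance alone gives about 1 in 20 groups. Among controls, Spp1 on day 26 was 418 in replicate 2 and 753 to 831 in the others (gap over range 0.855), Timp1 on day 5 was 32.1 in replicate 2 and 63.3 to 74.7 in the others (0.788), Mdm2 on day 8 was 172 in replicate 1 and 220 to 235 in the others (0.784), and Mki67 on day 8 was 68.3 in replicate 3 and 36.7 to 40.7 in the others (0.845). At 1 mg/kg, replicate 2 on day 26 had the lowest Cdkn1a, 37.3 against 63.6 to 74.6 (0.755), and the lowest Mdm2, 215 against 244 to 254 (0.767). Replicate 3 on day 8 had a Umod signal of 1160 against 2420 to 3080 (0.756), and replicate 2 on day 3 a Slc22a2 signal of 1110 against 929 to 978 (0.716). At 3 mg/kg, Mdm2 on day 26 was 279 in replicate 5 and 263 to 267 in the others (0.737), Top2a on day 26 was 11 in replicate 2 and 27.3 to 34.8 in the others (0.746), and Slc34a1 on day 3 was 4100 in replicate 2 and 4560 to 4710 in the others (0.769). The GAPDH 3'/5' ratio was 1.42 in control day 3 replicate 5 (others 1.3 to 1.32; 0.768), 1.47 in control day 5 replicate 3 (1.35 to 1.38; 0.726) and 1.38 in 1 mg/kg day 3 replicate 5 (1.28 to 1.31; 0.716).

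Probe sets without a gene name were tested in the same way and enter only the counts over every kept probe set. Of 5315 such probe sets, 1500 changed at 3 mg/kg on day 8, 955 higher and 545 lower. The counts at 3 mg/kg were 709 on day 3, 254 on day 5 and 82 on day 26, and at 1 mg/kg 3 on day 3 and 17 on day 8.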

How the results depend on the processing

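The fits with the actin ratio or the Alb signal as a covariate, without the 2 arrays of 1 mg/kg on day 8 that stood apart, and all alternatives for the immediate early and clock lists, were chosen after seeing the data, and the other alternatives before. Of the counts and summary values under alternatives set beforehand other than leaving out an array, 187 stayed within 1.5 times the reported value or on their side of the threshold and 42 did not; under the added ones 27 did and 10 did not. For named genes, 11659 comparisons under those alternatives kept direction and side of the threshold, 143 lost the call and 92 gained it. The 64 repeats of the exact tests of Havcr1, Lcn2, Clu and Cdkn1a kept every call. Signal over background limits dim genes: between 40.6% and 46.3% of probe sets on an array lay under the offset of 16. Where a value moved, the cause was not tested. Fits of the compared groups alone use fewer arrays and also only the spread of those groups, and these were not separated. For 3 against 1 mg/kg on day 3 such a fit gave 561 genes in place of 365, so fewer arrays alone do not account for every move.

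Without an offset, 3 against 1 mg/kg on day 26 gave 6 genes. An offset of 64 gave 1 gene for 1 mg/kg on day 5, 56 for 3 mg/kg on day 26 and 0 for 1 mg/kg on day 26. Quantile normalization gave 38 for 1 mg/kg on day 8, 33 for 3 mg/kg on day 26 and 2 for 3 against 1 mg/kg on day 26. The size of the excess of higher over lower genes at 3 mg/kg on days 3 and 8 depended on the scaling: after quantile normalization 2169 were higher and 2003 lower on day 8 and 566 and 548 on day 3, against 2502 and 1858 and 651 and 500 without it. With 75th percentile centring the split was 537 and 534 on day 3, and 142 and 193 for 3 against 1 mg/kg on that day. Where genes were called under each scaling, no share of higher genes moved by over 7.6 percentage points. The 60th percentile filter gave 0 for 1 mg/kg on day 26, and the mean of probe sets 7 for 1 mg/kg on day 3. Over every kept probe set, the counts were 2370 for 3 mg/kg and 17 for 1 mg/kg on day 3, 6931 for 3 mg/kg on day 8, 319 for 3 mg/kg and 0 for 1 mg/kg on day 26. They were 784 and 18 for 3 against 1 mg/kg on days 3 and 26, and 2888 for the change from day 5 to day 8. Array weights gave 1732 for 3 mg/kg and 22 for 1 mg/kg on day 3, 40 for 1 mg/kg on day 8, 157 for 3 mg/kg and 2 for 1 mg/kg on day 26. They gave 1047 and 56 for 3 against 1 mg/kg on days 3 and 26, and 381 for the change from day 3 to day 5. Fits of the compared groups alone gave 2553 for 3 mg/kg and 4 for 1 mg/kg on day 8, 8 and 0 on day 26. They gave 561, 183, 535 and 5 for 3 against 1 mg/kg on days 3, 5, 8 and 26, 1088 and 868 for the changes from day 5 to 8 and from day 8 to 26, and 118 for control day 26 against day 3. With an estimated correlation, 5 of 54 gene list shifts were called. With controls split, the correlation of the doses was 0.281, 0.083, 0.492 and 0.155 on days 3, 5, 8 and 26.

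With the replicate number as a block, 3 against 1 mg/kg on day 26 gave 13 genes, and no other count moved by over 1.5 times. The numbers did not mark pairs: correlations of deviations of same-numbered arrays ran from -0.168 to 0.259, every pair exceeded 0.1 in 0 of 12 pairs of groups, and 17 of 54 arrays correlated best with their own number.

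With the actin ratio as a covariate the counts were 499 for 3 mg/kg on day 3, 26 for 3 mg/kg on day 26, 175 and 1 for 3 against 1 mg/kg on days 3 and 26, and 63 for the change from day 3 to day 5. With the Alb signal they were 676 for 3 mg/kg on day 3, 105 for 3 against 1 mg/kg on day 3 and 57 for the change from day 3 to day 5. For control day 26 against day 3 the count was 2, and the change of Rup2 turned to 0.53 and that of Alb, the covariate itself, to 0. Alb separates those 2 control groups, so the count of 2 cannot show that their genes follow Alb. The actin ratio likewise separates 3 mg/kg on day 3 from the other groups of that day. The counts of 499 and 175 therefore cannot show which genes follow RNA quality. Without the 2 arrays, 1 mg/kg on day 8 gave 11 genes, and the shift of fibroblast and matrix genes turned to -0.08 (adjusted p = 0.0471; adjusted p = 0.772 with an estimated correlation).

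Leaving out each array in turn gave 7 to 11 genes for 1 mg/kg on day 3, 547 to 1096 for 3 mg/kg on day 5, 0 to 2 for 1 mg/kg on day 5, 12 to 127 for 1 mg/kg on day 8, 12 to 209 for 3 mg/kg and 0 to 3 for 1 mg/kg on day 26. It gave 179 to 532, 175 to 467 and 0 to 21 for 3 against 1 mg/kg on days 3, 5 and 26, 67 to 243 for the change from day 3 to day 5 and 66 to 236 for control day 26 against day 3. For 3 mg/kg the range was 828 to 1020 on day 3 and 3759 to 4524 on day 8. For 3 against 1 mg/kg on day 26, the count of 0 became 1 without 1 mg/kg replicate 4 or 3 mg/kg replicate 1 or 5, 12 without 1 mg/kg replicate 5 and 21 without 3 mg/kg replicate 2.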

Other observations

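Among the tests here, the splits of the arrays and the first liver and shared stress tests were planned before their results, and those on very long genes, age, the other liver tests and collection hour were chosen only after the results were seen. The lists behind them, and that of immediate early genes with its alternatives, were also written after the fit was seen. Immediate early genes, which cells transcribe within minutes of a stimulus, had 17 measured members. Of these, 14 had been seen among the leading genes when the list was written, so the counts below describe the list and do not test it. On day 26 at 3 mg/kg 12 rose, with a median of 0.97, including Fos by 1.87 ± 0.42 and Ccn1 by 1.82 ± 0.38 (n = 5 against 4), and on day 8 at 1 mg/kg 10 rose, with a median of 0.74. At 3 mg/kg on days 3, 5 and 8 the counts were 4, 9 and 10. The 3 members not seen before were Fosb, Egr3 and Nr4a1, with medians of 0.48 on day 26 at 3 mg/kg and 0.58 on day 8 at 1 mg/kg. As a list they did not pass (adjusted p = 0.2 and 0.14 with an estimated correlation in camera, over 24 tests).

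As measures of RNA quality, the actin 3'/5' ratio was 5.79 ± 0.72 and the GAPDH ratio 1.504 ± 0.125 at 3 mg/kg on day 26, against 5.10 ± 0.57 and 1.38 ± 0.04 in controls (mean ± SD). On day 8 at 1 mg/kg they were 6.09 ± 1.51, with the highest array at 8.58, and 1.415 ± 0.141, against 5.32 ± 0.48 and 1.378 ± 0.064 in controls. On day 26 at 3 mg/kg, 7 genes of the immediate early list rose with the actin ratio as a covariate (median 0.95) and 5 with the GAPDH ratio (0.85). Without 1 array the count there ran from 1, without control replicate 1, to 13, without 3 mg/kg replicate 2. It was 3 without control replicate 4 or 3 mg/kg replicate 1 or 4, 5 without control replicate 2, 6 and 8 without 3 mg/kg replicates 3 and 5, and 12 without control replicate 3. On day 8 at 1 mg/kg, 2 rose without replicates 1 and 3 (median 0.65), 10 with the actin ratio and 9 with the GAPDH ratio. Without control replicate 1, 2 or 3 the count there was 5, 4 or 3, and without 1 mg/kg replicate 1 or 3 it was 6 or 1.

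Of 9 high-phase clock genes 4 rose on day 3 at 3 mg/kg, and of 5 low-phase ones 4 fell. Nr1d1 rose by 1.77 ± 0.24, Per3 by 1.19 ± 0.16, the transcription factor Dbp by 1.19 ± 0.26 and Nr1d2 by 0.79, while Cry1 (-0.87 ± 0.20), Bmal1 (-0.82 ± 0.15), Nfil3 (-0.63) and Npas2 (-0.48) fell. Per1 (-0.23), Hlf (-0.20), Per2 (0.06), Bhlhe41 (0.28), Tef (0.34) and Clock (-0.13) did not pass. Nr1d1, Per3, Dbp, Bmal1 and Cry1 had been seen among the leading genes when the lists were written. Without these 5, neither list passed: the 6 high-phase genes left had a median of 0.17 and the 3 low-phase ones -0.48 (adjusted p = 0.76 and 0.14 with an estimated correlation). The mean Hbb signal was 845 ± 227 (SD, n = 5) at 3 mg/kg on day 3 and 2320 ± 446 in its controls.

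The clock shift may reflect killing at another hour, which is not given in the sources used here. The median change of high-phase minus low-phase genes was 0.97 at 3 mg/kg on day 3 (0.65 without the 5 genes seen before) and 0.55 at 1 mg/kg (0.24). At 3 mg/kg it was 0.64, 0.61 and 0.43 (0.41, 0.23 and 0.26) on days 5, 8 and 26. At 1 mg/kg on those days it was 0.41, 0.36 and 0.19 (0.16, 0.17 and 0.02). Both doses share the controls of their day, so a shift of those controls alone could move both values the same way. Hour would give a shift with dose only if killing followed the order of dose, which is not given either. Hour and drug therefore cannot be told apart. A shared stress response could also move these genes: within groups, the mean of immediate early genes and the clock score had r = -0.106 over 57 arrays (permutation p = 0.563; rho = -0.023, permutation p = 0.876; r = 0.021 without the 2 farthest arrays; 1 relation computed). That lies just past the bound of 0.1 set before, which leaves this explanation undecided as well.

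Transcripts of very long genes were lower on day 3 at 3 mg/kg. A trend with gene length had been seen in exploration before the list was written, so the test is not blind to the pattern, although its 42 measured members had not been seen to fall beforehand (the 11 that had been are left out). Their median change lay below that of all genes by -0.143, with 33 of 42 below the median of all genes. Of the members, 8 were lower (Pde4d -0.45, Ccser1 -0.40) and Zbtb20 was higher at 0.27. At 1 mg/kg the value was -0.087. With an estimated correlation in camera, adjusted p was 0.000987 at 3 mg/kg and 0.000314 at 1 mg/kg. Both doses were compared with the same day 3 controls, so a shift of those controls alone could lower both values. The value at 1 mg/kg is therefore no independent repeat of that at 3 mg/kg. Such a shift was not tested, and the list was not tested between the doses. With the actin ratio as a covariate, the value at 3 mg/kg on day 3 was -0.146. That ratio ran from 4.48 to 5.08 in day 3 controls and from 5.74 to 6.02 at 3 mg/kg. Its slope comes from differences within groups, so this fit cannot exclude RNA quality as a cause of a difference between these groups. Against signal level, 0 of 10000 random lists matched on signal had a median as low. A candidate explanation is that cisplatin lowers transcripts of very long genes; the value was -0.053, -0.141 and 0.021 at 3 mg/kg on days 5, 8 and 26, with adjusted p = 0.169 with an estimated correlation on day 8, and other properties of long genes were not tested.

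Alb and Rup2 signals were high on day 3 arrays of every dose, and a small amount of liver RNA may account for them. The bound set against this before the test, that under 1 in 10 other liver transcripts would lie above every later control on every day 3 array, was met by 2 of 26 (7.69%), by a margin of under 1 transcript. It is not read as excluding liver RNA, a choice made after the result: 20 of the 26 have medians under a signal of 16 in later controls, near the floor, and 22 of 26 had a higher mean in day 3 controls than in later controls, where 10000 lists matched on signal had a median of 13 and 99.98% of them lay lower. Of the 26, 18 were highest on the day 3 array with the highest Alb, 1 mg/kg replicate 2, where chance gives 1.73. Against age, day 5 controls kept 5.66% of the difference in Alb between day 3 and day 26, whereas day of collection stays open, untested.

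Other splits of the same arrays into groups of the same sizes were tested in 100 draws, or in all 56 for day 5 at 1 mg/kg and for 3 against 1 mg/kg on that day. By the bound set before, under 5% of splits as large, chance could be excluded for 3 mg/kg on days 3, 5 and 8. These gave 1151, 1028 and 4360 genes, against 43, 227 and 2725 in the highest other split. On day 26 the count was 88, and 2 of 100 splits were as large, the real one included. That met the bound, although another split gave 154. The bound was also met for 1 mg/kg on days 3 (11 genes, highest other split 4) and 8 (61, 14) and for control day 26 against day 3 (237, 82). For 3 against 1 mg/kg it was met on days 3 (365, 72), 5 (464, 97) and 8 (2704, 2288). For the changes of effect, the splits mixed treated and control arrays within each day. That removes the effect on both days, so these splits cannot test whether it changed. The counts from day 3 to 5, 5 to 8 and 8 to 26 were 177, 1909 and 1748, against 198, 1741 and 2681 in the highest other split. In the first and last, 2 of 100 splits were as large, the real one included. For 1 mg/kg on day 5 only the real split of 56 gave 2 genes and the highest other gave 1, but leaving out 1 array gave 0 or 1 in 6 of 8 fits, so a margin of 1 gene carries it. The 16 tests of splits were not adjusted for their number. Chance could not be excluded for 1 mg/kg on day 26 (1; 1, with 5 of 100 as large, the real one included) or for 3 against 1 mg/kg on day 26 (0; 8, with 100 of 100 as large). Other splits that involve day 8 at 3 mg/kg called up to 1741 to 2725 genes, and which animals those splits gather was not examined.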
